A study of Mus musculus with 40 samples.

How the data were processed

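RNA sequencing of mouse hematopoietic progenitor cells was used, labelled by source as hematopoietic progenitor or multipotent progenitor cells, at P0 and P14. Per the labels' protocols, RNA was extracted with a Qiagen micro kit and libraries were made from SMART-amplified cDNA. The deposited values are raw read counts per Ensembl gene, made with featureCounts 1.4.5 per the submitters' processing notes. The genome build, annotation release and strand setting behind these counts are not stated in the sources used here. The P14 table holds 41388 gene IDs and that of P0 holds 40548, after 276 repeated entries identical to others were dropped from the P0 table. Gene symbols and coordinates come from GENCODE M21 on GRCm38, which matched 40254 IDs of each table.

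Of 40 samples in 10 groups in the labels, 36 in 9 groups had a column of counts and were used, 4 per group. No column carries the name of the P0 NHD13 samples, so NHD13 against wild type at P0, the P0 interaction and the age difference of the NHD13 effect are not analysed here, and the P0 fit uses 12 libraries in place of the 16 planned. A further 4 columns of the P0 table are named as libraries 5 to 8 of Flt3-ITD with NHD13, match no sample in the labels and were not used. Whether they are the P0 NHD13 samples under another name or further libraries is not known here. No 2 libraries of a group were copies of each other: over 54 pairs the chi-square per degree of freedom between their counts was at least 9.85 (median 23.4, highest 151).

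Each age was fitted alone with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, estimated dispersions, robust quasi-likelihood fit and F test), with 1 mean per group and all groups of the age in the fit. The filter left 14394 genes at P14 and 14359 at P0, with 99.9% of the counts. Age differences came from a fit of both ages together over 14984 genes, in which the wild type of each age is its own reference. Age and sequencing run are not separated by the labels, so those differences compare effects, each against its own wild type. This removes a constant offset per gene. A difference of effects can still come from the run as well as from age. The biological coefficient of variation was 0.164 at P14 (18 residual degrees of freedom), 0.301 at P0 (9) and 0.222 in both together (27). A gene passes at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. The tool's moderated standard error gives each SE. Interactions and age differences are differences of log2 fold changes.

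With 13.7 to 39.3 M counts per library, precision is set by the spread between libraries rather than by counting for most genes. Counts were simulated from the real means, dispersions and depths, with 200 changed genes taken from those with a mean log2 CPM of at least 2. All other genes had the same mean in every group. Recovery and the share of calls on unchanged genes depend on how many genes change. The values below therefore hold for 200 changed genes and not for comparisons with many more. Recovery of weaker genes was not simulated. For Flt3-ITD against wild type at P14 (14142 genes), 6.74% of edgeR's calls were on unchanged genes. There edgeR recovered 53.7% of 1.5-fold, 95.5% of 2-fold and 100% of 4-fold changes. For Flt3-ITD with Runx1-heterozygous these were 55.2%, 95.5% and 100% (14143 genes), and for the Runx1 interaction 25.4%, 70.1% and 98.5% (14143 genes). At P0 they were 11.9%, 65.7% and 97% for Flt3-ITD (14097 genes) and 11.9%, 62.7% and 97% for Flt3-ITD with NHD13 (14098 genes), so P0 changes under 2-fold were mostly missed. For the age difference of the Flt3-ITD effect they were 10.4%, 67.2% and 93.9% (14702 genes). No recovered change had the wrong sign. In the same simulations the share of DESeq2 calls on unchanged genes was 14.2% for Flt3-ITD at P14, 11.7% for Flt3-ITD at P0 and 18.2% for Flt3-ITD with NHD13 at P0.

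In all, 20 gene lists with 352 entries were fixed before the counts were seen: type I interferon-stimulated, MHC class I and interferon-gamma-linked, STAT5 target, MAPK feedback, hematopoietic stem cell, granulocyte-monocyte progenitor, lymphoid, megakaryocyte-erythroid, HOX, fetal progenitor, cell cycle, MYC and ribosome biogenesis, and immediate early genes, markers of 6 other cell types, and sex-linked genes. Each was tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with the correlation estimated from the data. Members that pass are counted over all genes and again adjusted over the list alone. The interferon score is the mean log2 CPM (prior count 2) over its 39 genes, compared by exact permutation over 70 arrangements.

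Genes were named by a rule fixed in advance. It takes the targeted genes, then the 6 highest and 6 lowest passing genes per comparison with wild type (mean log2 CPM of at least 2, every library of a group above every library of the other). It takes 4 each for the direct comparison of the combined genotypes, interactions and age differences (there without the separation), and up to 3 passing members per direction of each list. Of 521 named and passing pairs of gene and comparison, 386 stayed past the threshold under every alternative, and the report describes genes from these only, apart from the targeted genes and the 2 genes of Flt3-ITD at P0. That restriction was chosen after the values were seen. Where a group had 0 counts, folds are given against a floor of 3 counts over the group, and where it had 1 to 3, as a ratio with its 95% counting interval. Reads shared between paralogs (globin, Oas1, Ifit3 and H2 genes) make those genes uncertain.

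Alternatives were RLE size factors, no filter, the DESeq2 1.42.0 Wald test, only the groups compared, the replicate number as a block, and each library left out in turn. A sex term and limma voom with weights per age were added after the data were seen. Sex was read from Xist against Y-linked counts.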

Results

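RNA was sequenced from mouse hematopoietic progenitor cells, the multipotent cells from which the blood lineages arise, carrying combinations of 3 mutations linked to acute myeloid leukemia. Flt3-ITD is an activating internal duplication in a receptor tyrosine kinase, NUP98-HOXD13 (NHD13) is a fusion of a nuclear pore gene with a homeobox gene, and Runx1 encodes a transcription factor of the blood lineages. At 14 days of age (P14) there were 24 libraries in 6 groups: wild type, Flt3-ITD, NHD13, Runx1-heterozygous, Flt3-ITD with NHD13, and Flt3-ITD with Runx1-heterozygous. At birth (P0) there were 12 libraries in 3 groups: wild type, Flt3-ITD, and Flt3-ITD with NHD13. Each group had 4 libraries. P14 libraries held 13.7 to 27.3 M counts (median 19.9) and P0 libraries held 17.3 to 39.3 M (median 28.8). The labels do not say that the 4 libraries of a group are separate animals, so the p-values measure the spread between these samples. Below, log2 fold changes are given ± SE, every comparison has 4 libraries in each group, and adjusted p is Benjamini-Hochberg over all tested genes from an edgeR quasi-likelihood fit. A camera call given with a single adjusted p also held with an estimated correlation.

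The targeted genes moved as follows in whole-gene counts, which do not check the altered allele itself. Hoxd13 (ENSMUSG00000001819, GRCm38 chromosome 2, 74668310 to 74671599, plus strand) had 342 counts over the NHD13 libraries and 216 over those of Flt3-ITD with NHD13 at P14, against 1 over the wild type. These are ratios of 300 (95% counting interval 53.4 to 11900) and 191 (33.9 to 7580). At P0 it had 420 counts in Flt3-ITD with NHD13 against 3 in the wild type, a ratio of 192 (65.3 to 936). Nup98 (ENSMUSG00000063550, chromosome 7, 102119398 to 102210176, minus strand), the fusion partner of Hoxd13, rose in NHD13 libraries (0.57 ± 0.11, adjusted p = 0.00052) and in Flt3-ITD with NHD13 (0.40 ± 0.11, adjusted p = 0.0111) at P14. There it averaged 34 (SD 4.86) CPM in the wild type, 34.4 (SD 4.21) in Flt3-ITD, 50.6 (SD 2.85) in NHD13, 44.9 (SD 4.06) in Flt3-ITD with NHD13, 32.5 (SD 2.48) in Runx1-heterozygous and 29.9 (SD 4.4) in Flt3-ITD with Runx1-heterozygous. At P0 it averaged 56.1 CPM (SD 8.27) in Flt3-ITD with NHD13, 34.4 (SD 5.18) in the wild type and 29.5 (SD 8.38) in Flt3-ITD. Flt3 (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489, minus strand), a cytokine receptor of early progenitors, averaged 1370 CPM (SD 138) in the P14 wild type and 733 (SD 37.9) in Flt3-ITD. In the other P14 groups it averaged 1020 (SD 104) in NHD13, 1080 (SD 126) in Runx1-heterozygous, 650 (SD 33.3) in Flt3-ITD with NHD13 and 602 (SD 34.4) in Flt3-ITD with Runx1-heterozygous. It fell by 0.90 ± 0.09 in Flt3-ITD (adjusted p = 2.34e-08), by 0.43 ± 0.09 in NHD13 (adjusted p = 0.00049), by 1.08 ± 0.09 in Flt3-ITD with NHD13 (adjusted p = 1.86e-10) and by 1.19 ± 0.09 in Flt3-ITD with Runx1-heterozygous (adjusted p = 3.53e-11). At P0 Flt3 averaged 940 CPM (SD 205) in the wild type, 459 (SD 76.1) in Flt3-ITD and 528 (SD 205) in Flt3-ITD with NHD13.

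Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149, minus strand) averaged 49.6 CPM (SD 7.58) in the P14 wild type and 52.2 (SD 5.1) in the libraries labelled Runx1-heterozygous, so its whole-gene count was not lower there. It averaged 79.9 (SD 4.13) in Flt3-ITD with Runx1-heterozygous, where it rose (0.69 ± 0.13, adjusted p = 0.000196). In the other P14 groups it averaged 59.3 (SD 8.57) in Flt3-ITD, 44.5 (SD 9.42) in NHD13 and 52.9 (SD 4.32) in Flt3-ITD with NHD13, and at P0 58.9 (SD 7.05) in the wild type, 52.8 (SD 10.9) in Flt3-ITD and 49.1 (SD 12.2) in Flt3-ITD with NHD13.

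In Flt3-ITD at P14, 553 genes rose and 685 fell. Ccn3, a secreted matricellular signalling protein, rose (7.94 ± 0.57, adjusted p = 1.12e-09), as did Rasgrf2 (4.51 ± 0.38), a Ras exchange factor. Socs2, a cytokine-signalling suppressor that STAT5 induces, rose by 4.37 ± 0.24 (adjusted p = 1.76e-10). Enah (4.13 ± 0.43), Tcrg-C1 (3.67 ± 0.31) and Rab44 (3.08 ± 0.26) also rose. The cadherin Cdh17 (-5.58 ± 0.78, adjusted p = 6.39e-05), the sialyltransferase St8sia1 (-4.24 ± 0.38), the small GTPase Gem (-3.67 ± 0.19) and the activin subunit Inhba (-3.08 ± 0.75) fell. Without wild-type library 3 the total of 1238 became 767, and with a sex term in the fit it became 691.

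Among the STAT5 target genes of Flt3-ITD, 5 of 15 rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 2.82e-08). Id1 (2.02 ± 0.24), a helix-loop-helix inhibitor, was among those that rose, and Bcl6 (-2.12 ± 0.37), a repressor that STAT5 opposes, fell. Among the MAPK feedback genes, some of which dampen signalling through ERK, 1 of 11 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 4.01e-11). They include Spry4 (-4.28 ± 0.66), Etv5 (-2.81 ± 0.24) and Dusp6 (-2.14 ± 0.27). Of the immediate early and stress genes, 6 of 10 fell (8 adjusted over the list alone, as few as 2 lower without wild-type library 3, camera adjusted p = 9.95e-08). Egr1 was at -3.11 ± 0.43 and Nr4a1 at -1.49 ± 0.25. Of the MYC and ribosome biogenesis genes, 11 of 21 rose (13 adjusted over the list alone, as few as 5 higher without wild-type library 3, camera adjusted p = 2.2e-09, adjusted p = 0.0528 with an estimated correlation), among them Srm (0.58 ± 0.14), Nolc1 (0.47 ± 0.10) and Polr1b (0.46 ± 0.10).

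Of the granulocyte-monocyte progenitor genes in Flt3-ITD, 7 of 21 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.000228, adjusted p = 0.137 with an estimated correlation). The granule protease Ctsg (2.999 ± 0.42), the lipopolysaccharide co-receptor Ly86 (2.42 ± 0.41) and the monocyte-lineage factor Irf8 (1.78 ± 0.18) rose. Of the hematopoietic stem cell genes, 2 of 23 rose and 7 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0781): Ifitm1 (2.75 ± 0.11) rose, and the stem cell regulators Ndn (-1.18 ± 0.24), Hlf (-0.98 ± 0.12) and Mecom (-0.69 ± 0.12) fell. Of the megakaryocyte-erythroid genes, 3 of 22 fell (3 adjusted over the list alone, as many as 5 lower without wild-type library 2, camera adjusted p = 0.000113). Car2 was at -1.38 ± 0.10 and Gp9 at -0.86 ± 0.21. The thymus-homing receptor Ccr9 (-2.31 ± 0.32), Il12a (-0.95 ± 0.16) and Bcl11a (-0.49 ± 0.11) fell in the lymphoid priming and B-lineage list, where 1 of 19 rose and 3 fell (5 and 4 adjusted over the list alone, as many as 5 lower without Flt3-ITD library 2, camera adjusted p = 0.519). Of the HOX cluster and cofactor genes, 3 of 16 fell (4 adjusted over the list alone, as few as 1 lower without Flt3-ITD library 2, camera adjusted p = 0.0127, adjusted p = 0.137 with an estimated correlation). Hoxa9 was at -0.58 ± 0.11.

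Of the type I interferon-stimulated genes, which cells switch on in antiviral defence, 8 of 39 rose (10 adjusted over the list alone, as few as 2 higher without wild-type library 2, as many as 14 higher without wild-type library 1) in Flt3-ITD (camera adjusted p = 1.92e-08, adjusted p = 0.392 with an estimated correlation). Oas1g, whose reads can be shared with its paralog Oas1a, rose by 1.53 ± 0.29. Of the MHC class I and interferon-gamma-linked genes, 7 of 20 rose (9 adjusted over the list alone, where 2 fell, as few as 3 higher without wild-type library 3, camera adjusted p = 0.000195, adjusted p = 0.38 with an estimated correlation). The guanylate-binding proteins Gbp3 (0.68 ± 0.12) and Gbp7 (0.45 ± 0.10) rose. Markers of other cell types moved beside these. The macrophage marker Adgre1 (3.02 ± 0.28), the dendritic marker Clec10a (1.90 ± 0.22) and the basophil marker Mcpt8 (2.12 ± 0.38) rose, while Axl (-0.53 ± 0.12), Ccr7 (-1.003 ± 0.23) and the T cell receptor gene Trbc2 (-2.67 ± 0.28) fell. Of the T and NK cell markers, 2 of 5 fell (2 adjusted over the list alone, camera adjusted p = 0.0069, adjusted p = 0.0663 with an estimated correlation). Of the fetal progenitor genes, 1 of 9 rose (1 adjusted over the list alone, where 1 fell, camera adjusted p = 0.71). Of the 30 cell cycle genes, 0 of 30 passed edgeR's test, 6 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 0 lower (camera adjusted p = 0.71). All 4 Flt3-ITD libraries carried more Y-linked than Xist counts against 1 of 4 in the wild type.

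NHD13 at P14 switched on genes of the HOX clusters, which pattern the body axis and act in early blood cells. Hoxc8 had 1495 counts over the 4 NHD13 libraries and 0 in the wild type, at least 437-fold higher. Hoxc4 was 847-fold (95% counting interval 152 to 33500) higher, Hoxb7 534-fold (95% counting interval 95.4 to 21100) higher, and Unc13c, a synaptic vesicle gene, 1060-fold (95% counting interval 292 to 8730) higher. Hoxc5 (8.79 ± 0.38), Hoxc6 (8.20 ± 0.42), the ephrin receptor Epha3 (8.93 ± 0.35) and the developmental gene Mab21l2 (9.49 ± 0.29, adjusted p = 1.54e-19) also rose. In the HOX list, 11 of 16 rose and 1 fell (13 and 2 adjusted over the list alone, camera adjusted p = 1.21e-33); the cofactor Meis1 fell (-0.70 ± 0.09). The eosinophil granule genes Epx (-7.71 ± 1.72, adjusted p = 0.00349) and Prg2 (-6.67 ± 1.36, adjusted p = 0.00164), Ccr9 (-3.84 ± 0.35), Trbc2 (-3.44 ± 0.30), Zfp618 (-3.42 ± 0.47) and Emp1 (-3.42 ± 0.20) fell. In all, 1025 genes rose and 1260 fell.

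NHD13 libraries held fetal and megakaryocyte-erythroid transcripts. Of the fetal progenitor genes, 7 of 9 rose (9 adjusted over the list alone, camera adjusted p = 4.53e-17): the RNA-binding protein Lin28b (4.31 ± 0.17), the growth factor Igf2 (4.18 ± 0.67) and the imprinted RNA H19 (3.87 ± 0.48) rose. Of the megakaryocyte-erythroid genes, 13 of 22 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 3.81e-13), among them the carbonic anhydrase Car1 (6.08 ± 0.70) and the platelet factor Pf4 (5.74 ± 0.47). The hematopoietic stem cell list moved in both directions: 8 of 23 rose and 7 fell (10 and 9 adjusted over the list alone, camera adjusted p = 0.663). Nupr1 (3.71 ± 0.28), Vwf (3.24 ± 0.33) and Hoxb5 (2.90 ± 0.45) rose, and Esam (-3.17 ± 0.28), Ifitm1 (-2.64 ± 0.11) and Ndn (-2.39 ± 0.26) fell. In the granulocyte-monocyte progenitor list, 1 of 21 rose and 6 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.00327, adjusted p = 0.284 with an estimated correlation), with the receptor genes Csf1r (-2.11 ± 0.18) and Csf3r (-1.57 ± 0.18) and the factor Cebpa (-2.10 ± 0.34) lower. In the lymphoid list, 4 of 19 fell (4 adjusted over the list alone, camera adjusted p = 0.0236, adjusted p = 0.466 with an estimated correlation), including Dntt (-1.29 ± 0.20), which adds nucleotides to rearranging receptor genes.

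The STAT5 target genes went down in NHD13: 8 of 15 fell (8 adjusted over the list alone, camera adjusted p = 0.000758, adjusted p = 0.0734 with an estimated correlation). Socs3 was at -2.45 ± 0.45, Id1 at -1.81 ± 0.28 and Socs2 at -1.23 ± 0.26. Interferon genes rose too: of the type I list, 29 of 39 rose (31 adjusted over the list alone, camera adjusted p = 9.38e-18, adjusted p = 0.237 with an estimated correlation), led by Phf11d (2.10 ± 0.45), Oas1g (2.09 ± 0.29, paralog shared) and the interferon amplifier Irf7 (1.93 ± 0.39). In the MHC class I and interferon-gamma-linked list, 9 of 20 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.000758, adjusted p = 0.466 with an estimated correlation). The transactivator Nlrc5 was at 1.06 ± 0.20 and Irgm1 at 0.86 ± 0.15. In the mast cell, basophil and eosinophil list, 4 of 9 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.0382, adjusted p = 0.339 with an estimated correlation): the mast cell genes Cpa3 (4.49 ± 0.41), Mcpt4 (4.49 ± 0.93) and Ms4a2 (2.74 ± 0.53) rose while the eosinophil gene Prg3 (-4.75 ± 1.01) fell. In the T and NK cell list, 3 of 5 fell (4 adjusted over the list alone, camera adjusted p = 0.000758). Klrd1 was at -4.13 ± 0.82 and Cd4 at -0.68 ± 0.16. The iron carrier Trf, counted with the hepatocyte markers, fell (-0.60 ± 0.14); in that list 1 of 3 fell (1 adjusted over the list alone, camera adjusted p = 0.503). Of the MYC and ribosome biogenesis genes, 3 of 21 rose (3 adjusted over the list alone, as few as 1 higher without NHD13 library 2, camera adjusted p = 0.018, adjusted p = 0.479 with an estimated correlation).

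The libraries labelled Runx1-heterozygous differed from the P14 wild type in few genes: 37 rose and 75 fell. The basophil and mast cell receptor Cd200r3 (2.80 ± 0.47, adjusted p = 0.00308), the G protein Gna14 (1.68 ± 0.23), Tifab (1.63 ± 0.22), the protocadherin Pcdh7 (1.52 ± 0.17), Gimap4 (1.48 ± 0.21) and the platelet receptor Treml1 (1.45 ± 0.25) rose. The interleukin receptor Il18r1 (-2.21 ± 0.30, adjusted p = 8.5e-05), Chga (-1.87 ± 0.25), the glutamate receptor Gria2 (-1.79 ± 0.32), the NF-kappaB regulator Tnip3 (-1.69 ± 0.19) and the T cell receptor partner Cd6 (-1.57 ± 0.21) fell. The stem cell genes Slamf1 (1.09 ± 0.18) and Mllt3 (0.92 ± 0.11) rose, where 2 of 23 rose (2 adjusted over the list alone, where 1 fell, camera adjusted p = 0.0432, adjusted p = 0.453 with an estimated correlation). In the lymphoid list, 1 of 19 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.00441, adjusted p = 0.453 with an estimated correlation). The kinase Lck, among those that fell, was at -1.12 ± 0.15, while DESeq2 called 4 of the list higher and 2 lower. In the megakaryocyte-erythroid list, 2 of 22 rose (4 adjusted over the list alone, where 1 fell, camera adjusted p = 0.0432, adjusted p = 0.453 with an estimated correlation). Among the type I interferon-stimulated genes, 0 of 39 passed edgeR's test, 2 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 0 lower (camera adjusted p = 0.022, adjusted p = 0.749 with an estimated correlation). The MYC and ribosome biogenesis genes (camera adjusted p = 0.000118, adjusted p = 0.453 with an estimated correlation) were called up as a set by camera at its preset correlation. The immediate early genes (camera adjusted p = 0.0432, adjusted p = 0.453 with an estimated correlation) were called down as a set by camera at its preset correlation. Without wild-type library 1 the total of 112 became 176 and without wild-type library 3 it became 73; DESeq2 called 212.

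Flt3-ITD with NHD13 at P14 carried the HOX program together with the highest mean interferon score of the 6 P14 groups. Hoxc8 was at least 469-fold and Hoxb8 at least 64.3-fold higher than in the wild type, Hoxc4 932-fold (95% counting interval 167 to 36900) and Hoxb7 747-fold (95% counting interval 134 to 29600). Hoxc5 (8.63 ± 0.38), Hoxc6 (8.09 ± 0.42), Epha3 (8.24 ± 0.36) and Mab21l2 (8.24 ± 0.29) rose. The extracellular matrix gene Postn (-4.39 ± 0.32), the matrix protease Mmp2 (-4.29 ± 0.30), the vessel and stem cell genes Mmrn1 (-4.13 ± 0.26) and Esam (-4.07 ± 0.30), B4galt6 (-3.96 ± 0.23) and Trbc2 (-5.07 ± 0.34, adjusted p = 5.27e-12) fell. In all, 1468 genes rose and 1757 fell. In the HOX list, 10 of 16 rose and 1 fell (10 and 2 adjusted over the list alone, camera adjusted p = 7.34e-24), and in the fetal progenitor list 7 of 9 rose (9 adjusted over the list alone, camera adjusted p = 4.31e-13). Lin28b was at 4.17 ± 0.17 and H19 at 2.97 ± 0.49.

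Of the type I interferon-stimulated genes in Flt3-ITD with NHD13, 36 of 39 rose (37 adjusted over the list alone, camera adjusted p = 4.85e-36), with a median of 1.69. Phf11d (3.56 ± 0.46, adjusted p = 3.89e-06), Oas1g (2.94 ± 0.29, paralog shared) and Ifi27l2a (2.84 ± 0.33) moved the most. In the MHC class I and interferon-gamma-linked list, 14 of 20 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 1.54e-08, adjusted p = 0.14 with an estimated correlation): the interferon-inducible GTPases Iigp1 (2.07 ± 0.38) and Igtp (1.24 ± 0.17) and Nlrc5 (1.51 ± 0.21) rose, and the class II transactivator Ciita fell (-2.46 ± 0.40). Beside this, of the dendritic cell and MHC class II markers 1 of 9 rose and 4 fell (1 and 4 adjusted over the list alone, as few as 2 lower without wild-type library 4, camera adjusted p = 0.585). Clec10a was at 1.41 ± 0.22 and Itgax at -1.74 ± 0.38. Of the macrophage markers, 1 of 12 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.834). Adgre1 was at 2.01 ± 0.28. Of the immediate early genes, 3 of 10 fell (3 adjusted over the list alone, camera adjusted p = 0.0217, adjusted p = 0.278 with an estimated correlation). Of the T and NK cell markers, 1 of 5 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.00474).

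Signalling genes moved in Flt3-ITD with NHD13. Socs2 (4.14 ± 0.24), Id1 (1.43 ± 0.24) and Cish (0.97 ± 0.15), which report STAT5 activity, rose and Bcl6 (-2.96 ± 0.39) fell; in the STAT5 list, 5 of 15 rose and 3 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.0217, adjusted p = 0.202 with an estimated correlation). In the MAPK feedback list, 7 of 11 fell (8 adjusted over the list alone, camera adjusted p = 2.27e-06). Etv5 was at -2.68 ± 0.24, Spry4 at -2.61 ± 0.55 and Dusp6 at -1.92 ± 0.26. In the MYC and ribosome biogenesis list, 12 of 21 rose (13 adjusted over the list alone, camera adjusted p = 7.53e-06, adjusted p = 0.14 with an estimated correlation). Polr1b was at 0.60 ± 0.10 and Fbl at 0.53 ± 0.14. Of the stem cell genes, 8 of 23 rose and 9 fell (8 and 9 adjusted over the list alone, camera adjusted p = 0.274): Nupr1 (3.60 ± 0.28), Hoxb5 (2.75 ± 0.45) and Slamf1 (2.01 ± 0.18) rose, and Ndn (-3.38 ± 0.28) and Fgd5 (-2.54 ± 0.28) fell. In the megakaryocyte-erythroid list, 9 of 22 rose and 3 fell (9 and 3 adjusted over the list alone, as few as 1 lower without wild-type library 3, camera adjusted p = 0.0129, adjusted p = 0.0584 with an estimated correlation). Pf4 was at 4.32 ± 0.44. The myeloid genes Ly86 (2.13 ± 0.41) and Plac8 (1.55 ± 0.20) rose while Csf3r (-1.88 ± 0.18) and Csf1r (-1.73 ± 0.18) fell; in the granulocyte-monocyte progenitor list, 4 of 21 rose and 7 fell (4 and 9 adjusted over the list alone, as few as 2 higher without library 2 of Flt3-ITD with NHD13, camera adjusted p = 0.0458, adjusted p = 0.436 with an estimated correlation). The proliferation gene Mki67 fell (-0.60 ± 0.14) in the cell cycle list, where 8 of 30 fell (8 adjusted over the list alone, as few as 2 lower without library 2 of Flt3-ITD with NHD13, camera adjusted p = 0.23). In the lymphoid list 7 of 19 fell (7 adjusted over the list alone, where 2 rose, camera adjusted p = 0.0503). Ccr9 was at -3.04 ± 0.33 and Dntt at -2.01 ± 0.20.

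Lymphoid genes fell in Flt3-ITD with Runx1-heterozygous. Of the lymphoid priming and B-lineage genes, 18 of 19 fell (18 adjusted over the list alone, camera adjusted p = 2.39e-29): Ccr9 (-7.66 ± 0.48), the interleukin-7 receptor Il7r (-7.01 ± 0.54, adjusted p = 8.89e-10) and the recombinase Rag1 (-5.42 ± 0.84) fell. In the T and NK cell list, 3 of 5 fell (3 adjusted over the list alone, camera adjusted p = 0.000366). Trbc2 was at -8.08 ± 0.45 (adjusted p = 2.99e-13) and Klrd1 at -2.91 ± 0.73. Ccn3 (9.63 ± 0.55, adjusted p = 2.15e-12), the interleukin-2 receptor Il2ra (7.40 ± 0.52), Tcrg-C1 (6.70 ± 0.32), Enah (6.58 ± 0.42), Adgre1 (5.43 ± 0.30) and Rasgrf2 (5.30 ± 0.38) rose. Epx (-7.51 ± 1.72), Prg2 (-6.49 ± 1.35) and St8sia1 (-5.999 ± 0.44) fell. In all, 1537 genes rose and 1727 fell.

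Signalling genes moved in Flt3-ITD with Runx1-heterozygous. In the STAT5 list, 6 of 15 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 5.98e-10). Socs2 was at 5.05 ± 0.25, Id1 at 2.71 ± 0.24 and Bcl6 at -3.12 ± 0.40. In the MAPK feedback list, 1 of 11 rose and 9 fell (1 and 9 adjusted over the list alone, camera adjusted p = 4.08e-09): Dusp6 (-4.03 ± 0.29), Etv5 (-3.63 ± 0.26) and Spry4 (-3.57 ± 0.62) fell and Dusp5 (1.19 ± 0.20) rose. In the immediate early list, 8 of 10 fell (9 adjusted over the list alone, camera adjusted p = 9.99e-06). Egr1 was at -3.07 ± 0.43, Nr4a1 at -1.94 ± 0.26 and Jun at -1.62 ± 0.45. In the stem cell list, 4 of 23 rose and 8 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.889): Ifitm1 (3.44 ± 0.11) and the cell cycle inhibitor Cdkn1c (1.22 ± 0.21) rose, and Ndn (-2.70 ± 0.27) and Tek (-1.72 ± 0.26) fell. The fetal gene Hmga2 (1.14 ± 0.14) and Mycn (0.82 ± 0.17) rose. Ctsg rose (2.74 ± 0.41) while Csf3r (-0.70 ± 0.18) and Csf1r (-0.70 ± 0.17) fell. The erythropoietin receptor Epor (-2.11 ± 0.34) and Car2 (-1.77 ± 0.11) fell in the megakaryocyte-erythroid list, where 2 of 22 rose and 6 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.0991 with an estimated correlation). Of the MYC and ribosome biogenesis genes, 8 of 21 rose (8 adjusted over the list alone, as few as 5 higher without wild-type library 3, camera adjusted p = 0.00882, adjusted p = 0.478 with an estimated correlation).

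Of the type I interferon-stimulated genes in Flt3-ITD with Runx1-heterozygous, 1 of 39 rose and 3 fell (1 and 3 adjusted over the list alone, as many as 9 lower without library 3 of Flt3-ITD with Runx1-heterozygous, camera adjusted p = 0.57). Ifitm3 was at 1.23 ± 0.13 and Ifit2 at -0.49 ± 0.12. Markers of other cells moved too. In the macrophage list, 1 of 12 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.00304, adjusted p = 0.245 with an estimated correlation): Cd5l had 0 counts against 76 in the wild type, at least 24.6-fold lower, and Hmox1 (-3.14 ± 0.33) and Vcam1 (-2.78 ± 0.41) fell. In the dendritic list, 2 of 9 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.925). Clec10a was at 3.29 ± 0.23, Ly6d at -5.69 ± 1.14 and Ccr7 at -2.68 ± 0.25. In the endothelial and stromal list, 3 of 10 rose and 2 fell (5 and 2 adjusted over the list alone, as few as 1 higher without library 2 of Flt3-ITD with Runx1-heterozygous, as many as 6 higher without library 3 of Flt3-ITD with Runx1-heterozygous, camera adjusted p = 0.605). The collagen Col3a1 was at 2.06 ± 0.45, Stab2 at -3.11 ± 0.73 and Clec4g at -2.74 ± 0.67.

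The direct comparison of the 2 combined genotypes at P14 gave 1512 genes higher in Flt3-ITD with NHD13 and 1442 higher in Flt3-ITD with Runx1-heterozygous. Hoxc8 was 1360-fold (95% counting interval 245 to 53900) higher with NHD13, Hoxc4 904-fold (95% counting interval 162 to 35700) and Hoxc6 405-fold (95% counting interval 138 to 1970), and the ephrin receptor Epha3 was higher by 8.74 ± 0.38. Il2ra (-6.13 ± 0.46, adjusted p = 1.25e-10), Tcrg-C1 (-5.84 ± 0.30), Gdpd3 (-5.22 ± 1.35) and Tpm3-rs7 (-4.70 ± 1.14) were lower with NHD13. Of the type I interferon-stimulated genes, 36 of 39 were higher (36 adjusted over the list alone, camera adjusted p = 4.88e-41). Phf11d was at 3.23 ± 0.45, Ifit3 at 3.08 ± 0.57 and its paralog Ifit3b, which can share its reads, at 3.31 ± 0.48. Of the lymphoid genes, 18 of 19 were higher (18 adjusted over the list alone, camera adjusted p = 5.51e-18). The B cell receptor subunit Cd79a was at 6.53 ± 0.98, the surrogate light chain Igll1 at 5.91 ± 1.26 and Il7r at 5.90 ± 0.56.

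In the same direct comparison 12 of 22 were higher and 1 lower (13 and 2 adjusted over the list alone) in the megakaryocyte-erythroid list (camera adjusted p = 1.95e-06). Car1 was at 5.87 ± 0.79, Pf4 at 5.32 ± 0.48 and Ermap at 4.43 ± 1.23. In the fetal list, 4 of 9 were higher (4 adjusted over the list alone, camera adjusted p = 4.46e-08). Lin28b was at 4.36 ± 0.17 and Arid3a at 1.51 ± 0.17. Of the STAT5 targets, 2 of 15 were higher and 7 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.000169). The survival kinase Pim2 was at -1.39 ± 0.18, Socs3 at -1.93 ± 0.41 and Bcl2l1 at 0.63 ± 0.14. Among the macrophage markers, 7 of 12 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.314 with an estimated correlation). The complement gene C1qb was at 2.45 ± 0.34, Vcam1 at 2.33 ± 0.41 and Adgre1 at -3.42 ± 0.26. The stem cell genes Nupr1 (2.43 ± 0.25) and Slamf1 (2.06 ± 0.18) were higher with NHD13 and Esam (-4.17 ± 0.30) and Fgd5 (-2.93 ± 0.28) lower. Of the MHC class I and interferon-gamma-linked genes, 13 of 20 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 5.93e-07, adjusted p = 0.255 with an estimated correlation). Of the granulocyte-monocyte progenitor genes, 2 of 21 were higher and 7 lower (2 and 7 adjusted over the list alone, camera adjusted p = 0.043, adjusted p = 0.441 with an estimated correlation). Of the HOX genes, 12 of 16 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 1.04e-32).

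An interferon score, the mean log2 CPM over the 39 type I interferon-stimulated genes, was taken for each library; these genes answer to the same receptor and move together. It averaged 5.24 (SD 0.52) in the P14 wild type, 5.81 (SD 0.38) in Flt3-ITD, 6.37 (SD 0.19) in NHD13, 7.07 (SD 0.12) in Flt3-ITD with NHD13, 5.46 (SD 0.34) in Runx1-heterozygous and 5.11 (SD 0.49) in Flt3-ITD with Runx1-heterozygous. All 4 libraries of Flt3-ITD with NHD13 scored above all 4 of the wild type. The difference of 1.83 has an exact permutation p of 0.0286, the smallest that 70 arrangements of 4 against 4 can give, and 0.0763 after Benjamini-Hochberg over the 8 score tests. NHD13 against wild type (difference 1.13) and Flt3-ITD with NHD13 against Flt3-ITD with Runx1-heterozygous (difference 1.96) have the same p and adjusted p. Flt3-ITD against wild type differs by 0.56 (exact p = 0.1143, adjusted p = 0.2286). At P0 the score averaged 5.52 in the wild type (SD 0.56), 5.52 in Flt3-ITD (SD 0.36) and 6.02 in Flt3-ITD with NHD13 (SD 0.38), with an exact p of 0.2 for the last against the wild type (adjusted p = 0.32). The figure of scores by library shows every value.

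**Figure D1:**
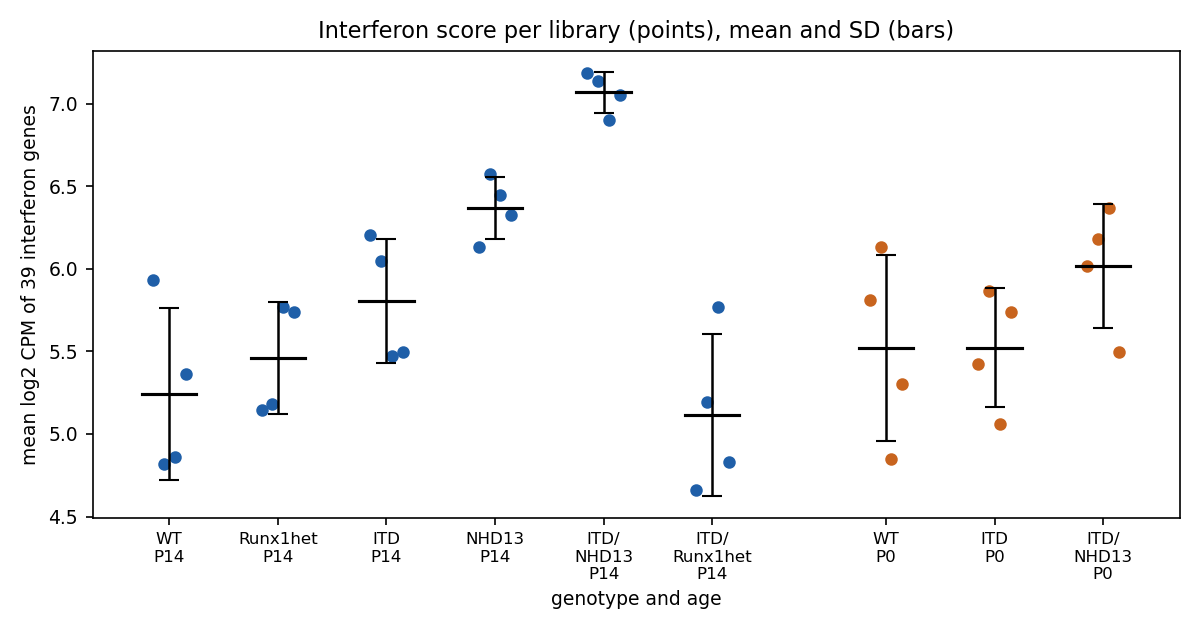
Interferon score of each library (points) with the mean and SD of each group, by genotype and age.

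The interaction of Flt3-ITD with NHD13 measures the departure of the combined genotype from the sum of the single effects on the log2 scale, and 37 genes were above the sum and 40 below. Ccr9 (3.12 ± 0.47, adjusted p = 0.0015), which each mutation alone lowered, and Gria2 (2.71 ± 0.42, adjusted p = 0.0013) were above it. The metalloproteinase inhibitor Timp3 (-4.15 ± 0.54, adjusted p = 0.000514) and the mast cell protease Cpa3 (-3.35 ± 0.52, adjusted p = 0.00342) were below it. In the stem cell list, 2 of 23 were higher and 1 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.243). Ifitm1 was at 1.09 ± 0.15. Among the type I interferon-stimulated genes, 0 of 39 passed edgeR's test, 2 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 0 lower, with a median of 0.23 (camera adjusted p = 0.0828). Of the granulocyte-monocyte progenitor genes, 2 of 21 were lower (4 adjusted over the list alone, camera adjusted p = 0.00779, adjusted p = 0.346 with an estimated correlation). The STAT5 target genes (camera adjusted p = 0.00837, adjusted p = 0.259 with an estimated correlation, 3 higher adjusted over the list alone), immediate early genes (camera adjusted p = 0.0259, adjusted p = 0.395 with an estimated correlation) and T and NK cell markers (camera adjusted p = 0.0415, adjusted p = 0.264 with an estimated correlation, 3 higher adjusted over the list alone) were called up as sets by camera at its preset correlation. The megakaryocyte-erythroid genes (camera adjusted p = 0.0346, adjusted p = 0.259 with an estimated correlation, 1 lower adjusted over the list alone), cell cycle genes (camera adjusted p = 0.0415, adjusted p = 0.686 with an estimated correlation), MYC and ribosome biogenesis genes (camera adjusted p = 0.00837, adjusted p = 0.45 with an estimated correlation) and macrophage markers (camera adjusted p = 8.46e-05, adjusted p = 0.259 with an estimated correlation, 4 lower adjusted over the list alone) were called down as sets by camera at its preset correlation. The total of 77 became 50 without Flt3-ITD library 3, 49 without Flt3-ITD library 4, 46 and 41 without libraries 3 and 4 of Flt3-ITD with NHD13, 41 without NHD13 library 4 and 40 without wild-type library 3. A sex term gave 47 and DESeq2 165.

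In the interaction of Flt3-ITD with Runx1-heterozygous, genes of early B cells lay below the sum of the single effects. The B cell receptor subunit Cd79a (-8.76 ± 1.19, adjusted p = 0.000319), the surrogate light chain genes Igll1 (-8.54 ± 1.55) and Vpreb3 (-7.84 ± 1.16), Ly6d (-7.97 ± 1.33) and Il7r (-7.46 ± 0.65, adjusted p = 4.53e-07) were lower. In the lymphoid list, 14 of 19 were lower (16 adjusted over the list alone, camera adjusted p = 3.78e-70). Lactotransferrin, Ltf (3.24 ± 0.59), Tcrg-C1 (3.06 ± 0.48) and the matrix gene Emilin2 (2.91 ± 0.57) were above the sum, and over all genes 93 were above and 149 below. In the granulocyte-monocyte progenitor list, 3 of 21 were lower (5 adjusted over the list alone, as many as 5 lower without library 3 of Flt3-ITD with Runx1-heterozygous, camera adjusted p = 1.45e-06, adjusted p = 0.06 with an estimated correlation). Ly86 was at -3.62 ± 0.58, Csf1r at -1.94 ± 0.24 and Irf8 at -1.38 ± 0.25. In the macrophage list, 4 of 12 were lower (7 adjusted over the list alone, where 2 were higher, camera adjusted p = 2.61e-10). Vcam1 was at -3.35 ± 0.55, C1qb at -2.76 ± 0.45 and Hmox1 at -2.64 ± 0.43. In the type I interferon list, 3 of 39 were lower (6 adjusted over the list alone, camera adjusted p = 8.07e-18, adjusted p = 0.237 with an estimated correlation). That count was 7 without library 3 of Flt3-ITD with Runx1-heterozygous and 0 by edgeR without Runx1-heterozygous library 3; with all libraries 15 lay under an unadjusted p of 0.05 and DESeq2 called 4 lower. Of the MYC and ribosome biogenesis genes, 1 of 21 was lower (4 adjusted over the list alone, camera adjusted p = 2.04e-06, adjusted p = 0.17 with an estimated correlation). Of the T and NK cell markers, 1 of 5 was lower (1 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.0541 with an estimated correlation). The fetal progenitor genes (camera adjusted p = 0.0381, adjusted p = 0.471 with an estimated correlation) were called up as a set by camera at its preset correlation. The MHC class I and interferon-gamma-linked genes (camera adjusted p = 0.00149, adjusted p = 0.492 with an estimated correlation) were called down as a set by camera at its preset correlation. Pim2 (1.51 ± 0.26) and Ifitm1 (1.07 ± 0.15) were above the sum, and Dusp6 (-1.75 ± 0.37), Tek (-1.63 ± 0.35), the erythroid factor Gata1 (-1.70 ± 0.27) and Trbc2 (-4.56 ± 0.59) below it. Without library 3 of Flt3-ITD with Runx1-heterozygous the total of 242 became 401, and DESeq2 called 374.

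At P0 Flt3-ITD changed 2 genes by edgeR. Cdh17, the cadherin that also fell at P14, fell (-2.55 ± 0.38, adjusted p = 0.0417), and the tetraspanin Tspan7 rose (1.96 ± 0.28, adjusted p = 0.0417). The total became 0 without any of Flt3-ITD libraries 1, 2 and 3 or wild-type libraries 2, 3 and 4, and 1 without Flt3-ITD library 4 or wild-type library 1. DESeq2 called 118 genes and 1469 lay under an unadjusted p of 0.05. With only these 2 groups in the fit edgeR called 117, with a sex term 0 and with the replicate number as a block 6. That block also made the dendritic markers a set called by camera at its preset correlation. Of the 1217 genes called at P14 and tested at P0, 85.7% had the same sign at P0, in other libraries. The Pearson correlation of the log2 fold changes was 0.401 over 13709 genes. All 4 Flt3-ITD libraries of each age carried more Y-linked than Xist counts, against 2 of 4 wild types at P0 and 1 of 4 at P14. Sex is thus uneven in the same direction at both ages, and this likeness alone does not separate genotype from sex. Of the MYC and ribosome biogenesis genes, 0 of 21 passed edgeR's test, 12 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 0 lower (camera adjusted p = 2.08e-10, adjusted p = 0.295 with an estimated correlation), and 9 rose adjusted over the list alone. Of the hepatocyte markers, which the fetal liver can contribute, 0 of 9 passed edgeR's test, 8 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 4 lower (camera adjusted p = 3.83e-06, adjusted p = 0.375 with an estimated correlation), and 8 fell adjusted over the list alone. P0 wild-type library 2 lay apart in these markers, with a mean of 5.48 against 0.84 to 2.45 in the other wild types. The STAT5 target genes (camera adjusted p = 0.0481, adjusted p = 0.487 with an estimated correlation, 2 higher adjusted over the list alone) were called up as a set by camera at its preset correlation. The MAPK feedback genes (camera adjusted p = 0.0086, adjusted p = 0.375 with an estimated correlation), megakaryocyte-erythroid genes (camera adjusted p = 0.000205, adjusted p = 0.375 with an estimated correlation, 8 lower adjusted over the list alone), immediate early genes (camera adjusted p = 0.00486, adjusted p = 0.375 with an estimated correlation) and T and NK cell markers (camera adjusted p = 0.0086, adjusted p = 0.375 with an estimated correlation, 1 lower adjusted over the list alone) were called down as sets by camera at its preset correlation.

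Flt3-ITD with NHD13 at P0 showed the HOX program at birth. Hoxc4 was 519-fold (95% counting interval 177 to 2520) higher than in the wild type and Hoxc8 468-fold (95% counting interval 83.5 to 18500). Mab21l2 (8.74 ± 0.58), Hoxc5 (8.49 ± 0.47), Epha3 (8.002 ± 0.52), the actin-binding Limch1 (5.61 ± 0.60) and the growth factor Igf1 (5.22 ± 0.31, adjusted p = 9.87e-08) rose. The phospholipase-like Plbd1 (-4.85 ± 0.76, adjusted p = 0.00235), the monocyte receptor Ccr2 (-3.29 ± 0.45), P2ry12 (-3.12 ± 0.53) and Id3 (-2.51 ± 0.32) fell. In all, 159 genes rose and 140 fell. In the HOX list, 9 of 17 rose (12 adjusted over the list alone, camera adjusted p = 3.88e-44), and in the fetal list 2 of 10 rose (5 adjusted over the list alone, camera adjusted p = 3.19e-07, adjusted p = 0.0857 with an estimated correlation). H19 was at 2.75 ± 0.42 and Lin28b at 1.67 ± 0.22. In the granulocyte-monocyte progenitor list, 3 of 19 fell (9 adjusted over the list alone, where 1 rose, camera adjusted p = 9.56e-08, adjusted p = 0.0857 with an estimated correlation). Csf1r was at -1.75 ± 0.27 and the granule enzyme Mpo at -1.28 ± 0.25. In the stem cell list, 4 of 23 rose and 1 fell (8 and 3 adjusted over the list alone, as few as 2 higher without wild-type library 1, camera adjusted p = 0.000514, adjusted p = 0.324 with an estimated correlation). Nupr1 was at 2.76 ± 0.33 and Mecom at 1.10 ± 0.20. Without wild-type library 1 the total of 299 became 198 and without wild-type library 4 it became 188; DESeq2 called 552.

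Of the type I interferon-stimulated genes in Flt3-ITD with NHD13 at P0, 0 of 39 passed edgeR's test, 16 lay under an unadjusted p of 0.05, and DESeq2 called 4 higher and 0 lower (camera adjusted p = 4.26e-08, adjusted p = 0.331 with an estimated correlation); 8 rose and 1 fell adjusted over the list alone. In the lymphoid list, 2 of 19 fell (7 adjusted over the list alone, camera adjusted p = 2.94e-05, adjusted p = 0.178 with an estimated correlation). Ccr9 was at -1.50 ± 0.19. In the T and NK cell list, 2 of 5 fell (2 adjusted over the list alone, camera adjusted p = 0.000451, adjusted p = 0.132 with an estimated correlation). Trbc2 was at -1.57 ± 0.25. Of the dendritic cell and MHC class II markers, 1 of 10 fell (5 adjusted over the list alone, camera adjusted p = 3.19e-07, adjusted p = 0.0962 with an estimated correlation). Of the hepatocyte markers, 0 of 9 passed edgeR's test, 8 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 3 lower (camera adjusted p = 0.000482, adjusted p = 0.36 with an estimated correlation); 8 fell adjusted over the list alone. The hepatocyte mean of P0 wild-type library 2 was 5.48, against 0.84 to 2.45 in the other wild types. Of the cell cycle genes, 1 of 30 fell (2 adjusted over the list alone, camera adjusted p = 0.000202, adjusted p = 0.173 with an estimated correlation). The MHC class I and interferon-gamma-linked genes (camera adjusted p = 0.00548, adjusted p = 0.299 with an estimated correlation, 2 higher adjusted over the list alone) were called up as a set by camera at its preset correlation. The endothelial and stromal markers (camera adjusted p = 0.00133, adjusted p = 0.178 with an estimated correlation, 2 lower adjusted over the list alone) were called down as a set by camera at its preset correlation. Of the 286 genes called at P0 and tested at P14, 233 were called at both ages. Of these, 227 went in the same direction, where 32.3 would be expected by chance. Of the 3125 genes called at P14 and tested at P0, 73.2% had the same sign at P0. The Pearson correlation of the log2 fold changes was 0.516 over 13709 genes.

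The effect of Flt3-ITD differed between the ages in 29 genes: 15 were higher at P14 and 14 lower. Higher or lower here refers to the log2 fold change against the wild type of the same age, not to the level. Age cannot be told apart from sequencing run in these differences. Rab44 (2.53 ± 0.36, adjusted p = 0.00069) and the monocyte-lineage factor Irf8 (1.66 ± 0.29, adjusted p = 0.00627) were higher at P14. St8sia1 (-2.81 ± 0.48), Gem (-2.24 ± 0.39), Etv5 (-2.15 ± 0.37) and Trbc2 (-2.07 ± 0.38, adjusted p = 0.00815) were lower at P14. In the granulocyte-monocyte progenitor list, 4 of 21 were higher (6 adjusted over the list alone, as few as 1 higher without P14 Flt3-ITD library 2, camera adjusted p = 1.02e-07). In the MAPK feedback list, where some members restrain growth factor signals, 1 of 12 was lower (4 adjusted over the list alone, camera adjusted p = 5.82e-06). Among the type I interferon-stimulated genes, 0 of 39 passed edgeR's test, 7 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 0 lower (camera adjusted p = 1.1e-08, adjusted p = 0.556 with an estimated correlation). Of the hepatocyte markers, 0 of 9 passed edgeR's test, 5 lay under an unadjusted p of 0.05, and DESeq2 called 1 higher and 0 lower (camera adjusted p = 0.0213, adjusted p = 0.592 with an estimated correlation), and 5 were higher adjusted over the list alone. Of the endothelial and stromal markers, 0 of 10 passed edgeR's test, 5 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 0 lower (camera adjusted p = 0.0118, adjusted p = 0.455 with an estimated correlation), and 4 were higher adjusted over the list alone. The MHC class I and interferon-gamma-linked genes (camera adjusted p = 0.000775, adjusted p = 0.495 with an estimated correlation, 2 higher adjusted over the list alone) were called up as a set by camera at its preset correlation. The immediate early genes (camera adjusted p = 0.0134, adjusted p = 0.455 with an estimated correlation, 1 lower adjusted over the list alone) were called down as a set by camera at its preset correlation. The total was 17, 15 and 12 without P14 Flt3-ITD libraries 1, 2 and 4, 13, 11 and 17 without P14 wild-type libraries 2, 3 and 4, 11 and 15 without P0 Flt3-ITD libraries 1 and 2, and 11 without P0 wild-type library 4. DESeq2 called 73 and voom 11.

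The effect of Flt3-ITD with NHD13 differed between the ages in 586 genes, 205 higher at P14 and 381 lower. As above, this ranks log2 fold changes against the wild type of the same age, not levels. Phf11d (3.28 ± 0.60, adjusted p = 0.000652), the pore-forming Mpeg1 (3.45 ± 0.68) and Ms4a4c (3.35 ± 0.56) were higher at P14, and Wfdc2 (-4.76 ± 0.72), Egr1 (-3.62 ± 0.65), Postn (-3.56 ± 0.67) and Trbc2 (-3.47 ± 0.42) lower. In the type I interferon list, 14 of 39 were higher (33 adjusted over the list alone, as few as 6 higher without P14 wild-type library 2, camera adjusted p = 1.71e-24, adjusted p = 0.107 with an estimated correlation). Ifi27l2a was at 2.47 ± 0.45. Of the endothelial and stromal markers, 3 of 10 were higher and 1 lower (6 and 1 adjusted over the list alone, as few as 0 higher without library 1 of P14 Flt3-ITD with NHD13, camera adjusted p = 0.00752, adjusted p = 0.174 with an estimated correlation); with all libraries 7 lay under an unadjusted p of 0.05 and DESeq2 called 3 higher and 1 lower. Of the dendritic cell and MHC class II markers, 0 of 10 passed edgeR's test, 6 lay under an unadjusted p of 0.05, and DESeq2 called 1 higher and 0 lower (camera adjusted p = 0.00112, adjusted p = 0.133 with an estimated correlation). In the stem cell list, 10 of 23 were lower (11 adjusted over the list alone, where 2 were higher, camera adjusted p = 1.86e-08, adjusted p = 0.107 with an estimated correlation). Ndn was at -3.46 ± 0.34 and the endothelial adhesion gene Esam at -2.71 ± 0.41. In the fetal list, 2 of 10 were higher (3 adjusted over the list alone, camera adjusted p = 0.000109, adjusted p = 0.107 with an estimated correlation). For Lin28b (2.52 ± 0.26) and Hmga2 (1.12 ± 0.21), which decline after birth in normal progenitors, the effect was higher at P14. Whether their level rose or fell with age was not measured. Socs2 (2.66 ± 0.64) and Id1 (2.06 ± 0.39) were higher at P14 too, where 2 of 15 were higher (2 adjusted over the list alone) in the STAT5 list (camera adjusted p = 0.103). Etv5 (-1.84 ± 0.36) and Ier3 (-1.09 ± 0.20) were lower, where 3 of 12 were lower (4 adjusted over the list alone) in the MAPK feedback list (camera adjusted p = 0.000109, adjusted p = 0.107 with an estimated correlation). Of the MHC class I and interferon-gamma-linked genes, 2 of 20 were higher (10 adjusted over the list alone, camera adjusted p = 0.00013, adjusted p = 0.174 with an estimated correlation). Of the megakaryocyte-erythroid genes, 1 of 24 was higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.174 with an estimated correlation). DESeq2 called 5 of them higher and 2 lower. Of the cell cycle genes, 1 of 30 was higher (2 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.379 with an estimated correlation). Of the MYC and ribosome biogenesis genes, 2 of 21 were higher (4 adjusted over the list alone, camera adjusted p = 2.43e-05, adjusted p = 0.133 with an estimated correlation). Of the immediate early genes, 2 of 10 were lower (5 adjusted over the list alone, camera adjusted p = 0.000304, adjusted p = 0.107 with an estimated correlation). Of the T and NK cell markers, 1 of 5 was lower (1 adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.133 with an estimated correlation). Voom called 360 genes in place of 586.

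Of the sex-linked genes, a technical check, 0 of 5 passed edgeR's test, 1 lay under an unadjusted p of 0.05, and DESeq2 called 0 higher and 1 lower in Flt3-ITD at P14 (camera adjusted p = 0.102). The wild type holds both sexes, so these genes vary widely within it and the test can miss an imbalance. By Xist and Y-linked counts 4 of 4 Flt3-ITD libraries were male at P14, against 1 of 4 in the wild type. The figure of calls shows the higher and lower genes of all 12 comparisons, and the figure of lists shows the list medians.

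**Figure D2:**
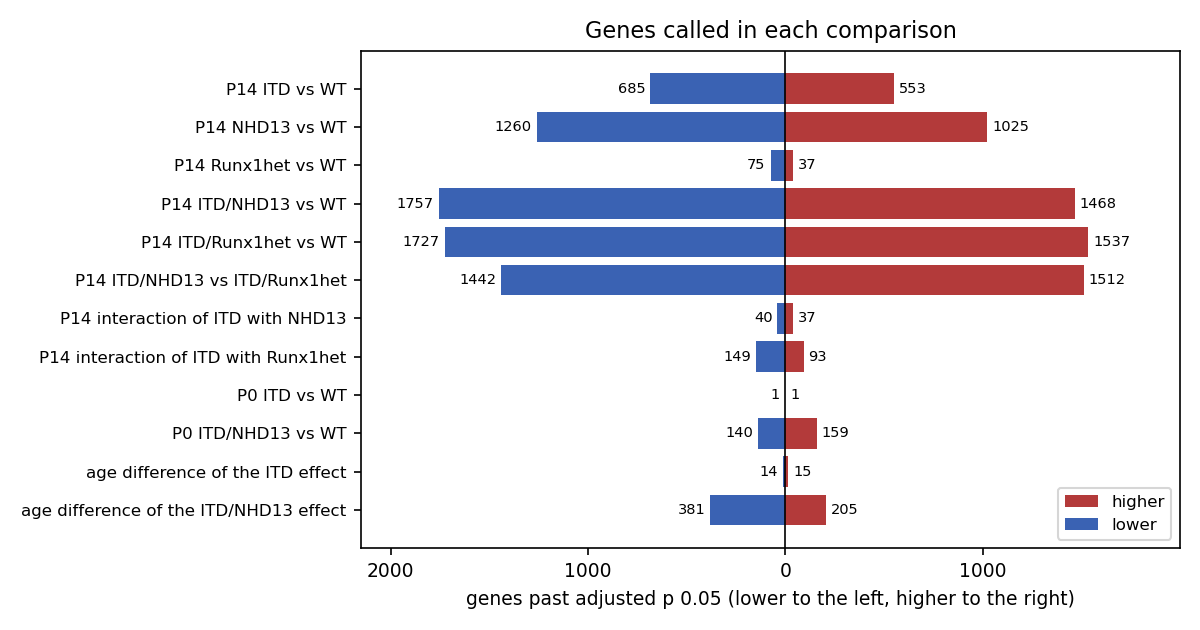
Genes that pass an adjusted p of 0.05 in each comparison, lower to the left and higher to the right.

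**Figure D3:**
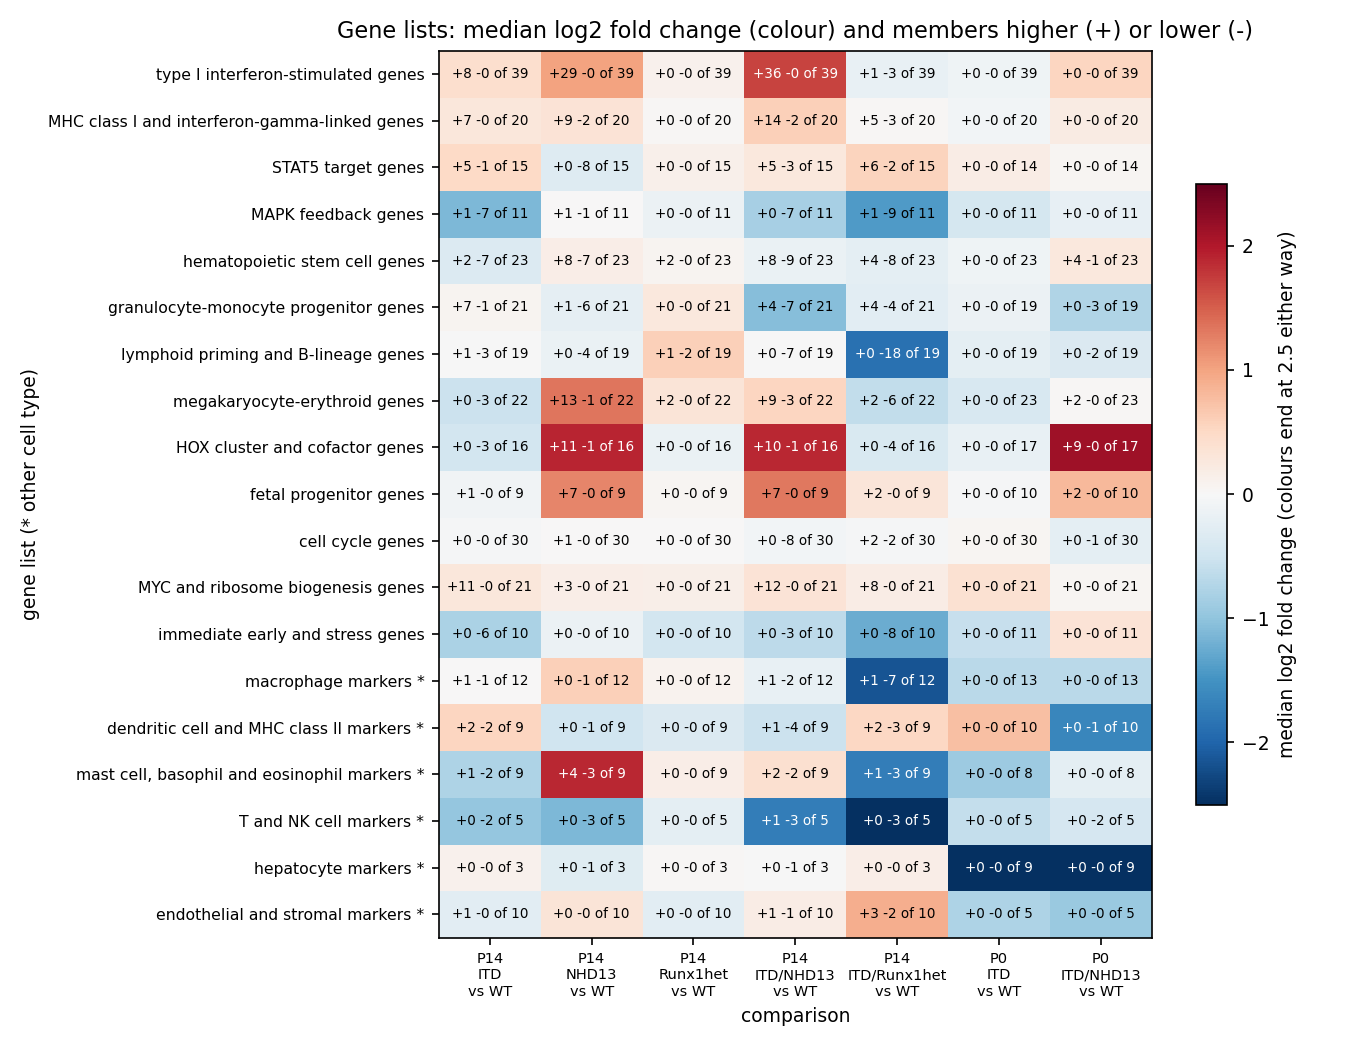
Median log2 fold change of each gene list against wild type, with the number of members higher and lower over all genes.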

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

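The tests of macrophage and dendritic RNA and of a purer sort were chosen after the results were seen; the other tests were not.

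Several measures were checked in each group for a library far from its 3 fellows. Of 99 pairs of measure and group, 5 had one, about the 5% expected by chance. Flt3 in NHD13 library 1 at P14 had 863 CPM against 1060 to 1090 in the others, and Runx1 in the same library 58.5 against 38.7 to 41.3. The macrophage marker mean was 1.25 in library 2 of Flt3-ITD with NHD13 at P0 against 1.51 to 1.55, and 2.70 in NHD13 library 2 at P14 against 2.15 to 2.20. The endothelial and stromal mean was -0.01 in Runx1-heterozygous library 4 against -0.64 to -0.54. A difference of effects between groups also brought up 77 genes for the NHD13 interaction, 242 for the Runx1 interaction, 29 for the age difference of Flt3-ITD and 586 for that of Flt3-ITD with NHD13.

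Other groupings of the same libraries were counted to see whether chance can give as many passing genes. Among 35 splits, only 1, the real one, reached the real count for 7 comparisons: Flt3-ITD (1238, highest other 233), NHD13 (2285, 50), Runx1-heterozygous (112, 5), Flt3-ITD with NHD13 (3225, 1056), Flt3-ITD with Runx1-heterozygous (3264, 663), the 2 combined genotypes (2954, 299) and Flt3-ITD with NHD13 at P0 (299, 6). No other split reached the real count in these 7, and 1 of 35 is the smallest share that the splits can give. Most other splits mix groups that differ in many genes, which can widen the spread and leave few calls. The splits alone therefore do not exclude chance. For Flt3-ITD at P0, 2 of 35 splits called at least the 2 genes of the real one (highest other 4), and chance cannot be excluded.

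For the interactions and age differences 100 splits were drawn within each pair of groups. As many genes were called by 2 of them for the NHD13 interaction (77, highest other 78), 3 for the Runx1 interaction (242, highest other 459), 4 for the age difference of Flt3-ITD (29, highest other 361) and 2 for that of Flt3-ITD with NHD13 (586, highest other 722), the real one included. Most of these splits mix groups that differ in many genes, which can widen the spread and leave few calls whatever the difference of effects, so chance is neither excluded nor shown there. The split with 361 genes calls several times the real 29, which a structure of the samples or genotype effects left in by uneven exchanges can give; neither was tested.

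The rise of the type I interferon genes in Flt3-ITD with NHD13 at P14 was weighed against RNA from other cells, depth and sex. Macrophage and dendritic markers, which such cells would bring, had a median log2 fold change of -0.36 over 21 genes (quartiles -0.79 and 0.33), against 1.69 (1.05 and 2.42) for the interferon genes. With a sex term 35 of 39 genes stayed higher (median 1.63). The marker test was chosen after the results were seen, and a median can miss cells that carry few of these markers. For the 21 markers as a set, the values argue against macrophages or dendritic cells as the whole source. The values with a sex term argue against sex as the whole cause. Thinning every library to the shallowest left a score difference of 1.82 (1.83 before). The bound set for that test was wrong, since thinning hardly moves a mean over well-expressed genes, so it decides nothing about depth. Depths by library overlapped, at 16.6 to 26.3 M in Flt3-ITD with NHD13 and 13.7 to 22.6 M in the wild type. Scores did not overlap, at 6.90 to 7.18 against 4.82 to 5.93. These depths and scores argue against depth as the whole cause. A rise in the progenitors themselves stays open. The inducing signal was not tested.

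The loss of lymphoid genes in Flt3-ITD with Runx1-heterozygous at P14 was weighed against a purer sort and sex. A purer sort would lower markers of every other cell type, and of 48 such markers 18 fell while 7 rose. Adgre1, Clec10a and Mcpt8, among those that rose, also rose in Flt3-ITD alone. Markers that respond to the genotype can rise in a purer sort too, so the test does not exclude one. With a sex term 18 of 19 lymphoid genes stayed lower. A purer sort, fewer lymphoid-primed cells within the sorted population and lower expression per cell all stay open.

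The genes of Flt3-ITD at P14 were weighed against sex, since all 4 of its libraries are male by Xist and Y-linked counts against 1 of 4 in the wild type. The sex effect measured in the 4 other P14 mutant groups accounts for 0.035 of the log2 fold changes of 1211 autosomal passing genes (0.0059 to 0.065 without each of 16 libraries). With a sex term all 1238 genes kept their direction and 680 of them still passed: the median size went from 0.66 to 0.62 and the median SE from 0.14 to 0.16. These values argue against sex as the whole cause, provided that the sex effect of those 4 groups holds in Flt3-ITD and the wild type. That was not tested, and sex is uneven between Flt3-ITD and the wild type. The genotype stays as a hypothesis.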

How the results depend on the processing

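The sex term and limma voom were chosen after the data were seen; the other alternatives were planned. Counts of passing genes kept within 1.5 times of the values in the report under RLE size factors and without the filter in all 12 comparisons. DESeq2 called 212 genes for Runx1-heterozygous, 165 for the NHD13 interaction, 374 for the Runx1 interaction, 118 for Flt3-ITD at P0, 552 for Flt3-ITD with NHD13 at P0 and 73 for the age difference of Flt3-ITD; the cause was not tested. Fitting only the groups compared gave 818 for Flt3-ITD at P14, 117 for it at P0 and 196 for Flt3-ITD with NHD13 at P0; the cause was not tested. The sex term gave 691 for Flt3-ITD at P14, 47 for the NHD13 interaction and 0 for Flt3-ITD at P0; it takes up a residual degree of freedom and shares variation with the all-male Flt3-ITD groups. Limma voom gave 11 for the age difference of Flt3-ITD and 360 for that of Flt3-ITD with NHD13; the cause was not tested. For the 0 of Flt3-ITD at P0, edgeR without the sex term had 1469 genes under an unadjusted p of 0.05, and DESeq2 called 118.

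Leaving out each library in turn gave 767 to 1738 for Flt3-ITD at P14, 1858 to 2660 for NHD13, 73 to 176 for Runx1-heterozygous, 2530 to 3491 for Flt3-ITD with NHD13, 2307 to 3860 for Flt3-ITD with Runx1-heterozygous, 2366 to 3089 between the combined genotypes, 40 to 103 for the NHD13 interaction and 168 to 401 for the Runx1 interaction. At P0 it gave 0 to 1 for Flt3-ITD and 188 to 315 for Flt3-ITD with NHD13, and for the age differences 11 to 36 and 399 to 858. Among the named genes, signs turned only for targeted genes that did not pass: Flt3 in the age difference of Flt3-ITD with NHD13 ranged from -0.44 to 0.02, Runx1 in the NHD13 interaction from -0.10 to 0.14, Nup98 in Flt3-ITD from -0.05 to 0.12, Runx1 in Flt3-ITD with NHD13 from 0 to 0.18, Nup98 in Runx1-heterozygous from -0.11 to 0.037 and Runx1 in Runx1-heterozygous from -0.024 to 0.15. The interferon score difference also turned, from -0.348 to 0.1 in Flt3-ITD with Runx1-heterozygous and from -0.225 to 0.203 in Flt3-ITD at P0. Of 521 named and passing pairs of gene and comparison, 135 were lost under any alternative and 0 changed sign under any.

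The labels do not say that same-numbered libraries share a source. Deviations of same-numbered libraries correlated above 0.1 in 8 of 60 pairs of libraries at P14 (-0.145 to 0.373) and 6 of 12 at P0 (-0.183 to 0.348), so a shared source at P0 is not ruled out. With the replicate number as a block, Flt3-ITD at P0 had 6 passing genes and the other counts stayed within 1.5 times (363 for Flt3-ITD with NHD13 at P0 and 701 for its age difference). In the list tests the block changed the direction of 2 that were not called, endothelial and stromal markers in Flt3-ITD with NHD13 at P14 (adjusted p = 0.981) and the interferon genes in Flt3-ITD at P0 (adjusted p = 0.898). It kept 108 of 110 calls. It ended those of the megakaryocyte-erythroid genes in Runx1-heterozygous (adjusted p = 0.0517) and the T and NK markers in the NHD13 interaction (0.065), and added the lymphoid genes in Flt3-ITD with NHD13 at P14 (0.0404) and the dendritic markers in Flt3-ITD at P0 (4.27e-05). With an estimated correlation 29 of the 110 list calls stayed and 81 ended; the larger correlation widens the null by construction. For NHD13 at P0, its interaction and its age difference no alternative was run, since no column of counts could be matched to their samples. At the P0 spread, changes under 2-fold are mostly out of reach.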

Other observations

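Mast cell, basophil and eosinophil genes, which mark granulocyte lineages that branch off early, moved apart in the combined genotypes at P14. Against wild type, the mast cell genes Ms4a2 (2.38 ± 0.53) and Cpa3 (1.58 ± 0.37) rose in Flt3-ITD with NHD13, where 2 of 9 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.614). In Flt3-ITD with Runx1-heterozygous the basophil protease Mcpt8 rose (1.53 ± 0.38) and the eosinophil gene Prg3 fell (-5.45 ± 1.10), where 1 of 9 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.184). Between the combined genotypes Ms4a2 was higher (3.28 ± 0.57) and Mcpt8 lower (-1.53 ± 0.38) with NHD13, where 3 of 9 were higher and 1 lower (7 and 1 adjusted over the list alone, as many as 5 higher without library 3 of Flt3-ITD with NHD13, camera adjusted p = 0.0349, adjusted p = 0.263 with an estimated correlation).

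Single genes of replication, mitosis and antigen presentation also differed between the combined genotypes. The replication helicase genes Mcm2 (0.41 ± 0.09) and Mcm6 (0.31 ± 0.07) were higher with NHD13 and the kinetochore gene Cenpf (-0.37 ± 0.09) lower, where 2 of 30 were higher and 5 lower (2 and 7 adjusted over the list alone, as few as 2 lower without library 2 of Flt3-ITD with Runx1-heterozygous, camera adjusted p = 0.343). The growth-arrest gene Btg2 (0.77 ± 0.13) and the immediate early gene Nr4a1 (0.96 ± 0.26) were higher with NHD13, where 3 of 10 were higher (3 adjusted over the list alone, camera adjusted p = 0.0767). The MHC class II genes H2-Aa (-1.70 ± 0.34) and H2-Eb1 (-1.60 ± 0.43), whose reads can be shared with related genes, were lower, where 2 of 9 were higher and 4 lower (2 and 4 adjusted over the list alone) in the dendritic list (camera adjusted p = 0.392).

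The hepatocyte marker mean of P0 wild-type library 2 was 5.48, against 0.84 to 2.45 in the other P0 wild-type libraries. Without it Flt3-ITD at P0 had 0 passing genes by edgeR, where 2 passed with it, 1469 lay under an unadjusted p of 0.05 and DESeq2 called 118. Leaving out Flt3-ITD library 1, 2 or 3 or wild-type library 3 or 4 also gave 0. Flt3-ITD with NHD13 at P0 had 230 without wild-type library 2, 214 of them among the 299. Leaving out each library in turn gave 188 to 315 there.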
